A study of Mus musculus with 8 samples.

How the data were processed

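Deposited processed files of 8 libraries were analysed. Mouse age was 8 weeks, and 50000 cells were sorted per library after depletion of lineage-positive cells, per the labels. RNA was isolated with a NucleoSpin RNA XS kit, and 10 ng was amplified with a SMARTer Ultra Low kit and sequenced as paired 150-base reads on a NovaSeq, per the labels. That kit does not mark the strand, so reads in overlapping genes cannot be assigned by strand. How such reads were counted is not stated. Per the submitters' processing notes, bcl2fastq, STAR 2.5.1a, Subread featureCounts 1.4.6-p5, Salmon 0.8.2, edgeR and limma were used with the GRCm38 genome; the notes do not state which file came from which step.

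Read counts per Ensembl gene were produced by the authors and deposited for 41388 genes in each library. CPM values were deposited by the authors and equal the count divided by the total count of the library, scaled as the name says. RPKM values were deposited by the authors and equal CPM per kilobase of the gene length given per the file headers. The log2 fold changes in the merged table were computed by the authors and deposited with confidence limits for 16691 genes. The p-value of each gene and its adjusted p-value in that table were computed by the authors, as deposited, by a model that is not stated. The score used by the authors, as deposited, is a signed linear fold change, negative for a fall. The 8 columns of per-library values in that table could not be matched to a stated step and were not used. Only the counts were fitted; CPM and RPKM served to check the files, and the authors' fold changes and adjusted p-values were used for comparison alone. Gene symbols came from the authors' table for 16691 genes and from GENCODE mouse release 21 for 23570 genes, and 1127 genes had none.

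Before the data were examined, the comparisons, the test, the filter, the 27 gene lists, 21 candidate genes, the rule for naming genes and most of the alternative settings were fixed. Genes were kept by filterByExpr in edgeR by group (minimum count 10, minimum total 15), which left 24780 genes. Libraries were scaled by TMM factors, and CPM in the text are TMM-scaled means with SD between libraries. All 8 libraries of 3 groups entered a single edgeR quasi-likelihood fit with robust estimation of dispersion. A gene was called at a Benjamini-Hochberg adjusted p-value under 0.05 with no minimum fold change, by the F test of each comparison. The SE of a log2 fold change is its size divided by the square root of F. For genes with 0 counts in every library of a group no fold change is stated; the fitted value, which depends on the prior count, is only plotted.

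Gene lists were tested with limma's camera on voom values with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 27 lists of a comparison. Camera with an estimated correlation and fry were the alternatives. Lists with under 3 measured genes were not to be tested. The lists were IL-6 and STAT3 targets and feedback; C/EBP family, cDC1, cDC2 and pre-cDC2, plasmacytoid cell, progenitor, monocyte, macrophage, and neutrophil and granule genes; IL-6 induced secreted and acute phase genes, MHC class II and maturation, interferon response, NF-kB and inflammation, immediate early and handling stress, MYC and ribosome biogenesis, S phase, G2 and M phase, cholesterol synthesis, glycolysis and hypoxia, integrated stress and unfolded protein response, p53 targets and apoptosis, ERK and PI3K feedback of growth factor receptors, B cell, T and NK cell, erythroid, megakaryocyte and platelet, and basophil, mast cell and eosinophil genes. They were written from general knowledge of the field. Counts adjusted over the list alone used the same p-values with the adjustment restricted to the members.

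Named genes were the 21 candidates; the 8 called genes with the largest rise and the 8 with the largest fall between Flt3L plus IL-6 and Flt3L (4 and 4 in the other comparisons); and up to 4 called members of each list by lowest p-value, or up to 2 by highest CPM where none was called. Genes chosen by size of change needed a mean of at least 10 CPM in the higher group, libraries of the groups that did not overlap, and a symbol other than that of a predicted gene.

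Alternatives were no filter, a filter of 5 CPM in 2 libraries, DESeq2 size factors, DESeq2's Wald test, limma voom with quality weights, the 10 highest genes left out, only the 2 groups compared, a block for replicate number, an adjusted p under 0.01, a minimum fold of 2, and each library left out in turn. After library measures were seen, 3 more were added: untreated replicate 1 and IL-6 replicate 2 left out together, list members counted with each library left out, and TMM factors from genes with a mean of at least 10 CPM. The relation of the IL-6 change to the Flt3L change was compared with 100 simulated sets of unchanged groups; the same with each library left out was added after the values had been seen.

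The procedure was tested on simulated data with the dispersions of the real libraries. Of 100 genes changed 2-fold, 15 were recovered (24.6% of those at 10 CPM or more), and of 100 changed 4-fold, 67 were recovered (94.8% of those at 10 CPM or more). Of 83 calls 1 was false, and a changed list was called while 0 of 26 unchanged lists were. The simulated genes varied independently, so this does not test camera under correlation between genes. A difference of 2-fold that was not called is therefore weak evidence of no change. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No library was left out of the fit. Transcript-level and splicing changes were not examined.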

Results

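Gene expression was measured by RNA sequencing in common dendritic cell progenitors (CDPs), the bone marrow cells that give rise to conventional and plasmacytoid dendritic cells. The cells were sorted from C57BL/6 wild-type mice as lineage-negative cells with intermediate cKit, with Flt3 and the M-CSF receptor, and without MHC class II or CD11c. Each library came from 50000 cells in 1 of 3 groups. Untreated cells gave 2 libraries, cells kept for 6 h with Flt3L (conditioned medium at 5%) gave 3, and cells kept for 6 h with Flt3L and IL-6 at 25 ng/ml gave 3. Flt3L is the growth factor that drives dendritic cell development, and IL-6 is an inflammatory cytokine that signals through gp130 and STAT3. The labels do not state whether the untreated cells spent the 6 h in culture, and no group had a control conditioned medium. A difference from the untreated group can thus come from Flt3L, from other contents of the conditioned medium or from culture. The labels also do not state that replicates came from separate mice or cultures, so p-values from edgeR measure the spread between these libraries, which may be technical.

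The total count was 17542489 and 39198244 in the untreated libraries, 44375032, 57013395 and 49236698 with Flt3L, and 47851777, 56196310 and 60261586 with Flt3L and IL-6. The limit set by 3 counts was 0.171 CPM in untreated replicate 1, the shallowest library, and 0.0765 CPM in untreated replicate 2. Both values are relative to the total count, without the TMM scaling used for the CPM of genes. These limits cover counting error only, since the reads carried no molecular identifiers. Between 24804 and 29839 genes had a count. With every library thinned to the smallest total, 29839 and 27349 genes had a count in the untreated libraries, 25737, 24651 and 27613 with Flt3L, and 25261, 22518 and 23226 with Flt3L and IL-6. Mitochondrial genes took 1.24% to 2.18% of the counts. Protein-coding genes took from 90.4% in Flt3L replicate 3 to 95.4% in IL-6 replicate 3. In Flt3L replicate 3 the predicted gene Gm42418 alone took 5.92%, the largest share of any gene in any library. The correlation of log2 CPM across genes was 0.924 between the untreated libraries, 0.948 to 0.958 among the Flt3L libraries and 0.942 to 0.949 among the IL-6 libraries. Genes are not independent replicates, so these correlations describe the libraries only. In a multidimensional scaling plot, the first dimension (30.7% of the variance) placed both untreated libraries apart from all treated ones. Positions on it ran nearly in the order of genes with a count after thinning, from untreated replicate 1 (3.37) to IL-6 replicate 2 (-1.92). Of the treated libraries, Flt3L replicate 3 (0.335) lay nearest to the untreated ones. Treatment and the number of detected genes thus cannot be told apart on this dimension. On the second dimension (14.8%) IL-6 replicate 2 stood apart, at 2.48 against -1.17 to 1.04 for the other libraries. Libraries of a group differed by more than counting error (chi-square per gene 54.3 to 202), which does not show whether they were separate cultures or repeated amplifications.

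The comparison of Flt3L plus IL-6 with Flt3L alone asked what IL-6 adds in progenitors that can become type 1 or type 2 conventional dendritic cells (cDC1 and cDC2). The largest rise among the named genes was that of Socs3, the feedback inhibitor of gp130 signalling (chromosome 11, 117966079 to 117970047, GRCm38), which rose from 2.88 ± 0.712 to 138 ± 49.1 CPM (mean ± SD, n = 3 each), a 47.9-fold change (log2 fold change 5.58, SE 0.52). Timp1, an inhibitor of metalloproteinases, rose from 2.74 ± 1.11 to 84.2 ± 11.3 CPM, and Ly6a, which encodes the progenitor surface antigen Sca-1, from 4.59 ± 2.75 to 93.8 ± 6.45 CPM. Il4ra, a receptor chain for IL-4 and IL-13, rose from 116 ± 34.2 to 651 ± 246 CPM. Irf8, the transcription factor that specifies cDC1 (chromosome 8, 120736358 to 120756694), fell from 1141 ± 199.8 to 480.2 ± 114 CPM, 2.38-fold lower. Cebpb, which encodes C/EBPb (chromosome 2, 167688915 to 167690418), rose from 4.81 ± 1.35 to 20.8 ± 5.82 CPM, 4.33-fold.

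Among the transcription factors that set dendritic cell fate, Irf8 and Cebpb lay close to the threshold, with adjusted p = 0.0497 and 0.0357 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Both calls were lost without any of Flt3L replicates 1, 2 or 3 or IL-6 replicates 1 or 2. The highest adjusted p was 0.156 for Irf8 (without Flt3L replicate 1) and 0.181 for Cebpb (without Flt3L replicate 2), while the log2 fold changes stayed between -1.45 and -1.06 and between 1.95 and 2.31. In the authors' deposited table the adjusted p was 0.00305 for Irf8 and 0.00343 for Cebpb. Zeb2, a repressor that opposes cDC1 development (chromosome 2, 44983634 to 45117395), stood at 84.3 ± 10.7 CPM with Flt3L and 127 ± 21.7 CPM with IL-6, and this 1.51-fold difference did not pass the test (adjusted p = 0.370, and 0.123 in the authors' deposited table). Zeb2 and Cebpb are named in the title of the study and are therefore not an independent choice. Id2, an inhibitor of E proteins in the cDC1 list (chromosome 12, 25093801 to 25096092), stood at 262 ± 32.5 and 415 ± 37.4 CPM (adjusted p = 0.188), and passed the threshold with DESeq2 and with voom, at an adjusted p of 0.0229 at the lowest. The log2 fold change was -0.65 for Batf3, 0.50 for Nfil3, -1.29 for Irf4, -0.06 for Klf4, 1.25 for Cebpd, 0.27 for Cebpa and 1.17 for Bcl6, none past the threshold; Bcl6 passed with no filter on low counts (adjusted p = 0.0169). Of the receptors, Il6st, which encodes gp130 (chromosome 13, 112464070 to 112510086), rose from 81.3 ± 2.40 to 175 ± 12.4 CPM (adjusted p = 0.0383). That call was lost without any single treated library, with an adjusted p up to 0.229 without Flt3L replicate 1. Flt3 (-0.57), Csf1r (0.12) and Il6ra (0.62) did not pass.

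**Figure D1:**
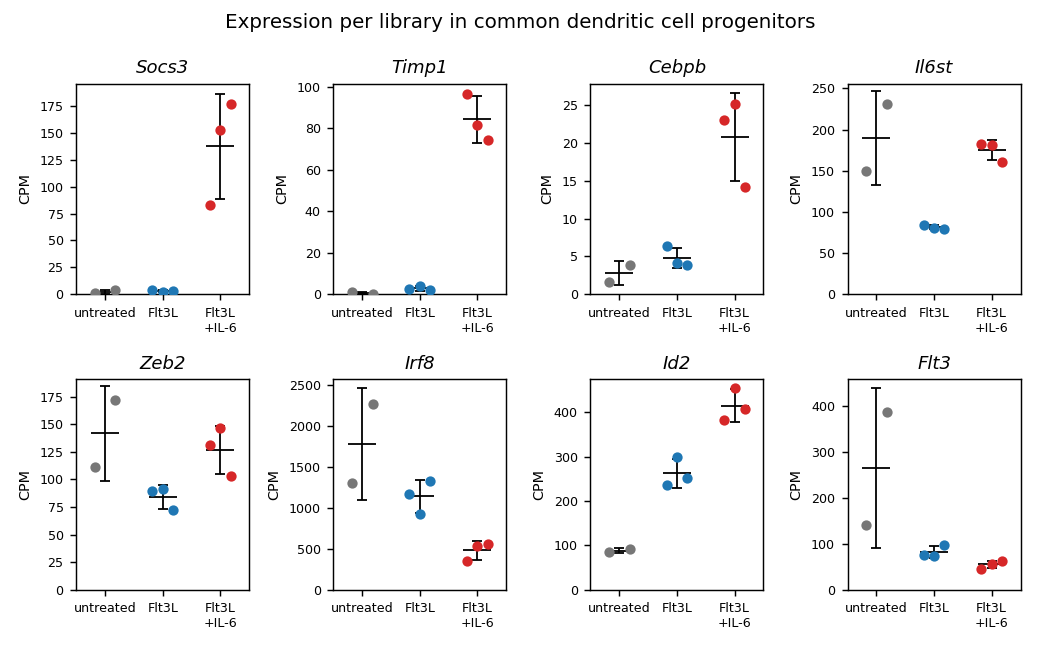
TMM-scaled CPM (vertical axes, from 0) of 8 genes in each group, with points for libraries, horizontal lines for group means and bars for SD (n = 2 untreated, 3 Flt3L, 3 Flt3L plus IL-6). Socs3 rose to 138 CPM with IL-6, Irf8 fell to 480.2 CPM, and Zeb2 was lowest with Flt3L alone at 84.3 CPM.

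IL-6 changed 120 of 24780 tested genes, of which 90 rose and 30 fell. Under the limits on expression and symbol set for named genes, the largest rises besides Socs3, Timp1 and Ly6a were those of Cyp4f37 (log2 fold change 4.18), Tarm1 (4.01), an immune receptor of myeloid cells, Spsb1 (3.92), Spint1 (3.85), a protease inhibitor, and Ifitm1 (3.68), an interferon-induced membrane protein that reached 1483 ± 280 CPM. Ifitm1 and Ifitm3 belong to a family of related genes, so their values are uncertain where reads could be split. Among called genes with a mean of at least 10 CPM in the higher group and a symbol other than that of a predicted gene, the largest falls were those of Sec31b (-2.80), Coq8a (-2.33), Upb1 (-2.27), Paqr5 (-2.20), Drc7 (-2.12), Epb41l4b (-2.07), Cd300c (-2.01) and Cd163 (-1.85), a scavenger receptor that went from 35.2 ± 8.59 to 9.78 ± 0.762 CPM. All of these 16 genes separated the Flt3L from the IL-6 libraries, as the choice of named genes required; chance gives such a separation for 10% of genes with 3 libraries against 3. Of 31 named genes that passed, 12 did so with each library left out in turn and 19 lost the call at least once, with an adjusted p of at most 0.229. Among the genes above, Spsb1 was lost without Flt3L replicates 1 or 3 or IL-6 replicate 2 (up to 0.106), and Sec31b without Flt3L replicates 1, 2 or 3 or IL-6 replicates 1 or 2 (up to 0.183). Upb1 was lost without Flt3L replicate 1 or IL-6 replicate 2 (up to 0.0753) and Epb41l4b without IL-6 replicate 2 (0.0917). Drc7 was lost without Flt3L replicates 2 or 3 or IL-6 replicates 1 or 3 (up to 0.0955), and Cd300c without Flt3L replicates 1 or 3 or IL-6 replicates 2 or 3 (up to 0.134).

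Of 25 measured targets and feedback regulators of IL-6 and STAT3, 6 rose, none fell and 19 did not pass, and 11 rose when adjusted over the list alone. With Socs3, Timp1 and Il4ra, these included Pim1 (125 ± 23.2 to 677 ± 94.9 CPM), a kinase induced by cytokines, Junb (11.3 ± 1.77 to 92.9 ± 57.0 CPM) and Il6st. Stat3 itself stood at 137 and 290 CPM (adjusted p = 0.0875), and passed with no filter, a filter of 5 CPM, DESeq2 and voom (0.00107 at the lowest) and without untreated replicate 1 or 2 (0.0430 at the lowest). The list was called by camera with its preset correlation (adjusted p = 1.87e-15) and by fry (adjusted p = 0.0141), while adjusted p = 0.0899 with an estimated correlation. The number of members called was 3 without Flt3L replicate 1 or 2. Pim1 lost its call without those 2 libraries in turn (adjusted p up to 0.0671), and Junb without Flt3L replicates 1, 2 or 3 or IL-6 replicates 2 or 3 (up to 0.209) or with TMM factors from genes of at least 10 CPM (0.0511). Of 7 genes of the C/EBP family only Cebpb rose (camera adjusted p = 0.00977; adjusted p = 0.189 with an estimated correlation). Of 15 IL-6 induced secreted and acute phase genes 1 rose, and 4 when adjusted over the list alone (camera adjusted p = 0.00122; adjusted p = 0.189 with an estimated correlation).

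Dendritic cell lists moved in no common direction. Of 21 cDC1 specification and identity genes, 1 fell (Irf8) and none rose, and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.833). Of 19 cDC2 and pre-cDC2 genes, 1 fell (Clec10a, a lectin of cDC2, 43.6 to 13.2 CPM; lost without Flt3L replicate 1 or IL-6 replicates 1 or 2, with adjusted p up to 0.0753) and none rose, and adjusted over the list alone 2 rose and 3 fell (camera adjusted p = 0.664). None of 17 plasmacytoid genes passed the test, with 13 log2 fold changes negative and 4 positive (camera adjusted p = 0.248). Of 18 MHC class II and maturation genes, Cd86, a costimulatory ligand, rose to 50.5 ± 6.45 CPM (log2 fold change 1.85) and H2-DMa, which loads peptide on MHC class II, fell from 532 ± 77.8 to 274 ± 5.22 CPM (camera adjusted p = 0.600). The call of Cd86 was lost without Flt3L replicate 2 or IL-6 replicate 1 (adjusted p up to 0.0695). That of H2-DMa was lost without untreated replicate 2, Flt3L replicates 1 or 2 or any IL-6 replicate (up to 0.203). None of 17 progenitor genes passed; the median log2 fold change was -0.57 (camera adjusted p = 0.0520, and 0.00917 without Flt3L replicate 1 and 0.00607 without IL-6 replicate 2), and Cd93 stood at 354 and 176 CPM (adjusted p = 0.0561). Cd93 passed as lower with DESeq2 size factors, no filter, a filter of 5 CPM, DESeq2, voom and TMM factors from genes of at least 10 CPM, at an adjusted p of 0.000559 at the lowest. By edgeR, 1 progenitor gene fell when adjusted over the list alone.

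Monocyte genes went up in part. Of 20 measured, 3 rose and none fell, and 6 rose when adjusted over the list alone (camera adjusted p = 0.000532; adjusted p = 0.508 with an estimated correlation). They were Vcan, a matrix proteoglycan (12.1 to 53.4 CPM), Fcgr1, the high-affinity IgG receptor (11.2 ± 7.09 to 56.7 ± 10.4 CPM), and Ifitm3 (524 ± 169 to 1444 ± 274 CPM). These 3 calls fell to 1 without Flt3L replicate 1 or IL-6 replicate 2 and to 0 without Flt3L replicate 2 or IL-6 replicate 1. Vcan was also lost without Flt3L replicate 3 and Fcgr1 without IL-6 replicate 3, and the highest adjusted p was 0.132 (Fcgr1, without Flt3L replicate 2). The list itself was not called without Flt3L replicate 3 (adjusted p = 0.686). Of 14 macrophage genes 1 fell (Cd163; camera adjusted p = 0.621), and adjusted over the list alone 2 rose and 2 fell. Camera gave an upward direction, while the mean log2 fold change was -0.32. Of 20 neutrophil and granule genes none passed the test over all genes (median -0.14). For this list camera gave an upward direction with adjusted p = 0.382, and 0.00436 without Flt3L replicate 1.

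Growth and stress lists leaned upward in many small steps. All 28 MYC and ribosome biogenesis genes had a positive log2 fold change (median 0.64, and 0.41 without IL-6 replicate 3); none passed over all genes, and 9 rose when adjusted over the list alone. Ncl, an abundant nucleolar protein, stood at 711 and 1247 CPM (adjusted p = 0.205; 0.0190 with no filter). All 24 genes of the integrated stress and unfolded protein response were positive too (median 0.66, and 0.49 without IL-6 replicate 3), and 13 rose when adjusted over the list alone; Hspa5, the main endoplasmic reticulum chaperone, stood at 839 and 1560 CPM (adjusted p = 0.188), and passed with no filter and with DESeq2 (0.00376 at the lowest). Both lists had a camera adjusted p of 1.44e-13, and adjusted p = 0.213 and 0.189 with an estimated correlation. Of 24 glycolysis and hypoxia genes 1 rose (Slc2a1, the glucose transporter GLUT1, 18.4 to 55.6 CPM), and 2 when adjusted over the list alone (camera adjusted p = 1.46e-07; adjusted p = 0.353 with an estimated correlation). The call of Slc2a1 was lost without Flt3L replicates 1, 2 or 3 or IL-6 replicates 2 or 3 (adjusted p up to 0.141). Of 24 immediate early and handling stress genes 3 rose, among them Ier3 (6.98 to 67.7 CPM, adjusted p = 0.000540), Jun and Junb, and 5 when adjusted over the list alone (camera adjusted p = 0.00173; adjusted p = 0.353 with an estimated correlation). Without Flt3L replicate 1 or 2 the number was 1. Camera also called the lists of interferon response (26 genes, adjusted p = 0.0279), NF-kB and inflammation (22, 0.0490), cholesterol synthesis (23, 0.000408) and p53 targets (20, 0.0287), with no member past the test over all genes. With an estimated correlation the adjusted p of these 4 lists was 0.795, 0.795, 0.545 and 0.189. Without Flt3L replicate 3 their camera adjusted p was 0.924, 0.520, 0.311 and 0.0947, and the direction of the interferon list turned downward. The NF-kB list was also lost with DESeq2 size factors, just above the threshold, and without IL-6 replicate 1 (0.337) or 2 (0.330), the interferon list without IL-6 replicate 2 (0.0559) and the p53 list without IL-6 replicate 2 (0.0571) or 3 (0.155). Adjusted over the list alone, 2 interferon genes and 1 p53 target rose. Lists of S phase (28 genes), G2 and M phase (26) and growth factor receptor feedback (25) were not called (camera adjusted p = 0.382, 0.494 and 0.857) and had no member past the test. Without Flt3L replicate 2 the S phase list (0.0139) and the G2 and M phase list (0.0359) were called.

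Among markers of other lineages, no member passed the test over all genes. B cell genes were called downward (14 genes, median -0.81, camera adjusted p = 0.0264; adjusted p = 0.189 with an estimated correlation; 0.195 by camera without IL-6 replicate 3 and 0.0671 without Flt3L replicate 1), with 3 members lower when adjusted over the list alone. The lists of T and NK cells (14 genes), erythroid cells (14), megakaryocytes (10) and basophils, mast cells and eosinophils (14) had medians of -0.49, 0.13, -0.57 and -0.17 and camera adjusted p = 1.00, 0.494, 0.494 and 0.749. The erythroid list was called without IL-6 replicate 2 (0.0389). Adjusted over the list alone, 1 basophil, mast cell or eosinophil gene rose and 1 fell.

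**Figure D2:**
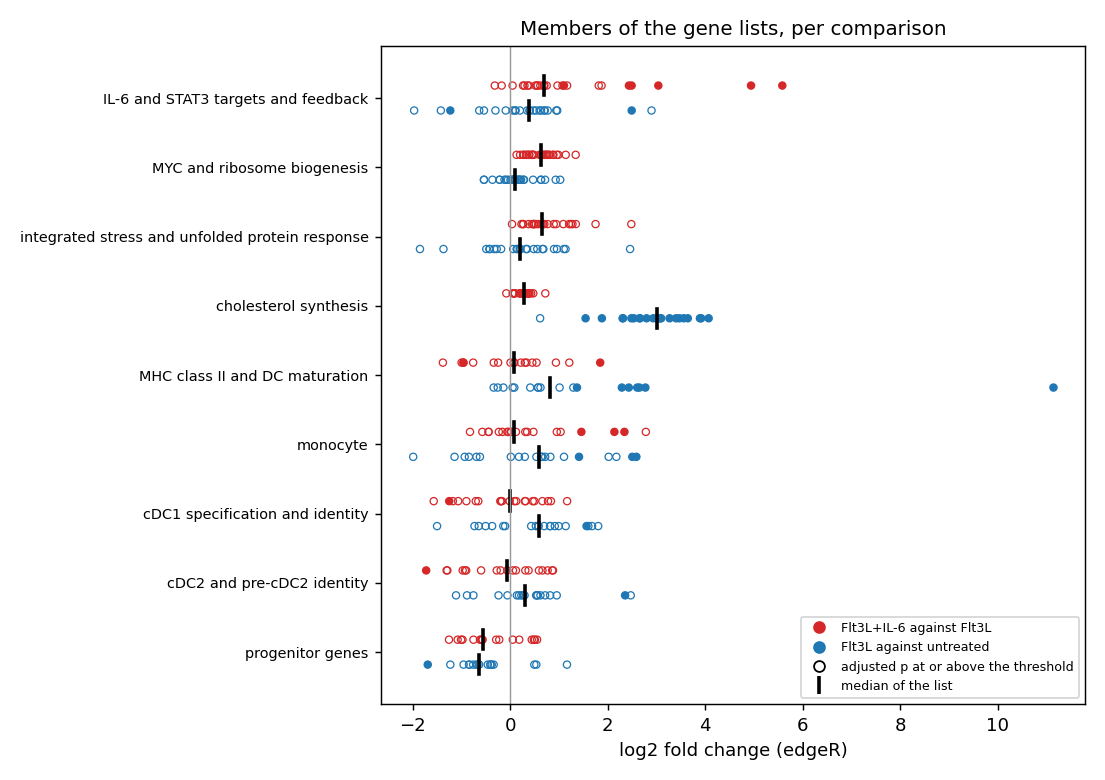
Log2 fold change of each measured member of 9 gene lists (horizontal axis, log2 units), for Flt3L plus IL-6 against Flt3L in red and Flt3L against untreated in blue. Filled points passed the test, open points did not, and black bars are list medians. Cholesterol synthesis genes lay at a median of 3.01 against untreated and 0.28 with IL-6; the point near 11 is Cd83, a fitted value against libraries with 0 counts.

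The test was edgeR's quasi-likelihood F test on all 8 libraries with adjusted p under 0.05. Of 13 lists called by camera with its preset correlation, 0 held with an estimated correlation and 1 by fry. The 120 calls became 45 without Flt3L replicate 1, 56 without Flt3L replicate 2, 54 without IL-6 replicate 2 and 185 without untreated replicate 1. Without adjustment edgeR's test had 2707 genes under 0.05, DESeq2 called 760 genes and voom 408. The authors' deposited table called 810 genes (515 up, 295 down), and held 117 of the 119 genes called here that it lists, all in the same direction. With scaling factors from genes of at least 10 CPM the split was 84 up and 71 down, since the median of all genes moved from -0.02 to -0.17. With a filter of 5 CPM it was 148 up and 117 down.

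The comparison of Flt3L with untreated cells, in 3 libraries against 2, gave the change without IL-6. Cholesterol synthesis genes rose nearly throughout. Hmgcs1, which makes HMG-CoA for sterol synthesis (chromosome 13, 119690462 to 119708086), rose from 43.3 ± 9.53 to 643 ± 227 CPM, and Lss, lanosterol synthase, from 7.79 ± 2.05 to 118 ± 34.8 CPM. Id3, an inhibitor of E proteins (chromosome 4, 136143497 to 136145755), had the largest rise among genes of at least 10 CPM in the higher group, from 1.43 ± 0.952 to 419 ± 61.6 CPM (log2 fold change 8.13, SE 0.45, adjusted p = 2.62e-06). The untreated libraries held 17 and 93 counts of Id3, so the size of its rise is uncertain. Id2 rose 2.96-fold from 88.5 ± 5.99 CPM (adjusted p = 0.00308; 0.0703 without untreated replicate 1). Abcg1, a sterol exporter (chromosome 17, 31057698 to 31115777), fell from 158 ± 31.9 to 17.0 ± 4.34 CPM (adjusted p = 0.000194).

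In this comparison 175 genes changed, of which 153 rose and 22 fell. Under the limits set for named genes, the largest rises after Id3 were those of Ccl22, a chemokine of mature dendritic cells (0.324 ± 0.426 to 19.8 ± 6.45 CPM), Dmwd (0.246 ± 0.220 to 13.7 CPM) and Clec4n, the lectin Dectin-2 (0.214 ± 0.177 to 12.4 CPM). The untreated libraries held 14 and 1 counts of Ccl22, 9 and 4 of Dmwd and 2 and 15 of Clec4n, so the size of these rises is uncertain, and with each library left out the log2 fold changes ranged from 5.00 to 9.62, 5.10 to 7.20 and 5.18 to 7.09. The call of Clec4n was lost with voom (adjusted p = 0.0608). Dmwd overlaps a neighbouring gene and the library kit did not mark strand, so its value is uncertain. Under the same limits the largest falls were those of Chdh (75.7 to 7.44 CPM), Abcg1, Upk1b (31.5 to 3.85 CPM; adjusted p = 0.0792 without untreated replicate 2) and Il31ra, an interleukin receptor chain that neighbours Il6st (51.9 to 7.93 CPM). Flt3, the receptor for Flt3L, fell from 265 ± 174 to 82.1 ± 12.7 CPM (adjusted p = 0.0409), and the call was lost without untreated replicate 2 (0.309), Flt3L replicates 1 or 2 or IL-6 replicates 1 or 2, and with only the 2 groups compared (0.0820). Il6st fell from 190 ± 57.1 CPM (adjusted p = 0.0262; 0.238 without untreated replicate 2), and this call was lost as well without Flt3L replicates 1 or 2 or IL-6 replicate 2 and with only the 2 groups compared (0.0750). Zeb2 stood at 142 ± 43.0 CPM in untreated cells (log2 fold change -0.75, adjusted p = 0.205), and passed with a filter of 5 CPM or with DESeq2, at an adjusted p of 0.0456 at the lowest; the authors' deposited table gave -0.70 and 0.0408. Irf8 (-0.64), Cebpb (0.78), Irf4 (2.47), Spi1 (1.17) and Csf1r (0.72) did not pass. Irf4 passed with no filter, DESeq2 and voom (0.000551 at the lowest) and without IL-6 replicate 3 (0.0472), and Spi1 with no filter and DESeq2 (0.00323 at the lowest).

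Of 23 cholesterol synthesis genes 21 rose and 2 did not pass, and 22 rose when adjusted over the list alone (median log2 fold change 3.01). The count stayed between 19 and 21 with each library left out. Fdps went from 187 ± 40.7 to 1433 ± 185 CPM and Msmo1 from 30.7 ± 4.95 to 384 ± 123 CPM. Camera gave an adjusted p of 2.23e-49 and fry 0.00325, with adjusted p = 0.0671 with an estimated correlation. Of 18 MHC class II and maturation genes 7 rose, also 7 when adjusted over the list alone. Cd74, the invariant chain, rose from 125 ± 5.62 to 854 ± 3.94 CPM (adjusted p = 6.90e-05), H2-Aa from 25.7 ± 4.98 to 139 ± 21.3 CPM and H2-Ab1 from 23.0 ± 9.17 to 140.2 ± 2.49 CPM. Cd83, a maturation marker, had 0 counts in both untreated libraries and 6.25 ± 2.24 CPM with Flt3L. The list had a camera adjusted p of 3.19e-11, a fry adjusted p of 0.00529 and adjusted p = 0.0807 with an estimated correlation. Of 20 p53 targets and apoptosis genes 3 rose, and 9 when adjusted over the list alone. The first of them was Cdkn1a, the cell cycle inhibitor p21 (28.8 ± 13.8 to 127 ± 12.7 CPM). This was the only list called with an estimated correlation (adjusted p = 0.0336), and camera gave 1.77e-08 and fry 0.00317. The estimated correlation was -0.0118 for this list and 0.503 for cholesterol synthesis. Lists with correlated members are thus judged more strictly, and the call does not rank this list above the others. The number of p53 members called was 1 without untreated replicate 2 or Flt3L replicate 1, and 5 without IL-6 replicate 3.

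Few members of the dendritic and myeloid lists passed the test, and no such list was called with an estimated correlation. Of 21 cDC1 genes 1 rose (Id2; camera adjusted p = 0.00234; adjusted p = 0.239 with an estimated correlation), and of 19 cDC2 genes 1 rose, Cd209a, a lectin (47.9 to 245 CPM; 0.0672 without untreated replicate 2), with a camera adjusted p of 0.0127 and adjusted p = 0.388 with an estimated correlation. Adjusted over the list alone, 2 cDC1 genes rose, and 3 cDC2 genes rose and 2 fell. Of 20 monocyte genes 3 rose (S100a4, Ifitm3 and Nr4a1), and adjusted over the list alone 5 rose and 2 fell (camera adjusted p = 0.0569). The number was 1 without untreated replicate 1, 0 without untreated replicate 2, 6 without Flt3L replicate 3 and 5 without IL-6 replicate 3. The list was called without untreated replicate 1 (0.0450), Flt3L replicate 3 (0.000280) and IL-6 replicates 2 or 3 (0.04999 and 0.04994). Of 14 macrophage genes Hmox1 and Axl rose, while the list median was -0.54 (camera adjusted p = 0.557). Both calls were lost without untreated replicates 1 or 2 or Flt3L replicate 1, and Hmox1 without IL-6 replicate 1 (up to 0.304 for Hmox1 and 0.198 for Axl). Siglech, a marker of plasmacytoid cells, rose from 52.2 ± 0.821 to 187 ± 34.2 CPM, the only 1 of 17 plasmacytoid genes to do so (camera adjusted p = 0.310), and 2 rose when adjusted over the list alone. Of 22 NF-kB and inflammatory genes 1 rose, and 11 when adjusted over the list alone (median 1.17; camera adjusted p = 1.50e-07; adjusted p = 0.296 with an estimated correlation). That gene, Nfkbia, lost its call without untreated replicates 1 or 2, Flt3L replicate 1 or IL-6 replicate 1 (up to 0.374) and with TMM factors from genes of at least 10 CPM (0.0600). G2 and M phase genes had no member past the test over all genes and 6 higher when adjusted over the list alone (camera adjusted p = 4.31e-08; adjusted p = 0.357 with an estimated correlation). Of 20 neutrophil and granule genes 2 fell, and 5 when adjusted over the list alone (camera adjusted p = 0.000530; adjusted p = 0.396 with an estimated correlation, and 0.0590 by camera without Flt3L replicate 3). Ms4a3, a marker of granulocyte and monocyte progenitors, went from 53.9 ± 14.1 to 12.7 ± 2.62 CPM (adjusted p = 0.0862 without untreated replicate 2). The other, Ctsg, lost its call without untreated replicates 1 or 2 or Flt3L replicate 1 (up to 0.206), so that neither passed without untreated replicate 2. Among markers of other lineages, Klrd1, the NK cell receptor CD94, rose from 12.5 ± 2.20 to 141 ± 17.2 CPM while Nkg7, a granule protein of NK cells, fell from 43.4 ± 0.466 to 10.4 ± 3.56 CPM. The call of Nkg7 was lost without untreated replicate 1 or 2 or Flt3L replicate 1, at an adjusted p of up to 0.0809. Dntt, the terminal transferase of lymphoid progenitors, fell from 107 ± 37.5 to 25.5 ± 5.07 CPM (0.119 without untreated replicate 2; also lost without Flt3L replicate 1).

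Camera also called 6 lists upward with at most 1 higher member each: glycolysis and hypoxia (adjusted p = 0.000117), growth factor receptor feedback (0.000133), immediate early genes (0.00741), IL-6 and STAT3 targets (0.0237), the stress response (0.0237) and the C/EBP family (0.0329). With an estimated correlation their adjusted p was 0.396, 0.239, 0.388, 0.388, 0.532 and 0.259. Of their called members, Aldoa was lost without untreated replicates 1 or 2, Flt3L replicates 1 or 2 or IL-6 replicates 1 or 2 (up to 0.356), Ccnd2 without any library but IL-6 replicate 3 (up to 0.463), and Nr4a1 without untreated replicates 1 or 2 (up to 0.143). Without untreated replicate 1 the immediate early (0.283), IL-6 and STAT3 (0.689) and stress response (0.300) lists were not called. The stress response list was also lost without Flt3L replicate 2 (0.0609), and the C/EBP family without untreated replicate 2 (0.0954) or Flt3L replicate 3 (0.0638).

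The 175 calls became 109 without untreated replicate 1, 85 without untreated replicate 2 and 105 without Flt3L replicate 1, and 299 and 401 without Flt3L replicate 3 and IL-6 replicate 3. With an untreated library left out, the remaining one was assumed to vary like the other groups. Of 14 lists called by camera, 1 held with an estimated correlation and 3 by fry. DESeq2 called 1386 genes (832 up, 554 down), voom 910 (434 up, 476 down) and no filter gave 909 (569 up, 340 down). The authors' deposited table had 1503 calls. It also called 169 of the 175 genes called here, all in the same direction. With scaling factors from genes of at least 10 CPM, 127 rose and 41 fell, and the median of all genes moved from -0.16 to -0.36.

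The comparison of Flt3L plus IL-6 with untreated cells took both cytokines together. Irf8 fell from 1782 ± 681 to 480.2 ± 114 CPM, 3.71-fold lower (log2 fold change -1.89, SE 0.27, adjusted p = 0.00180), and its call held with each library left out, at an adjusted p of at most 0.0318. Id2 rose 4.69-fold to 415 ± 37.4 CPM (adjusted p = 0.000137). Zeb2 (142 ± 43.0 and 127 ± 21.7 CPM, log2 fold change -0.16, adjusted p = 0.714) and Il6st (-0.12, adjusted p = 0.763) did not pass. Cebpb rose from 2.75 ± 1.62 CPM (log2 fold change 2.90, adjusted p = 0.00526; 0.0655 without untreated replicate 1). Ccr2, the chemokine receptor of inflammatory monocytes, rose from 557 ± 67.9 to 2328 ± 208 CPM, and Flt3 fell from 265 ± 174 to 55.3 ± 8.44 CPM.

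A total of 1271 genes changed, 730 up and 541 down. Under the same limits as above, the largest rises were those of Klrb1b, an NK receptor gene (0.0450 to 24.6 CPM), Id3 (1.43 to 399.8 CPM), Timp1 (0.425 ± 0.473 to 84.2 CPM) and Ocstamp, a gene of osteoclast fusion (0.134 ± 0.189 to 22.8 CPM). The untreated libraries held 1 and 2 counts of Klrb1b, 17 and 4 of Timp1 and 6 and 0 of Ocstamp, so the size of these rises is uncertain too; with each library left out the log2 fold change of Timp1 ranged from 6.81 to 9.82 and that of Ocstamp from 6.42 to 13.12. The largest falls were those of Muc3a (12.1 to 0.152 ± 0.209 CPM; log2 fold change -8.39 to -5.68 with each library left out), Phactr3 (27.3 ± 32.7 to 0.382 CPM; adjusted p = 0.203 without untreated replicate 1), Il31ra (51.9 to 1.56 CPM) and Sec31b (36.9 to 1.89 CPM). Of the 541 genes that fell, 247 had a mean under 5 CPM in untreated cells, their higher group. Of the 730 that rose, 18 had a mean under 5 CPM in both groups. The summed CPM of 1669 olfactory, vomeronasal and trace amine receptor genes, which blood progenitors are not known to express, was 539 and 197 in the untreated libraries, 100.2, 66.2 and 135 with Flt3L and 85.3, 67.3 and 61.2 with IL-6, and 7 of these genes were among those that fell.

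**Figure D3:**
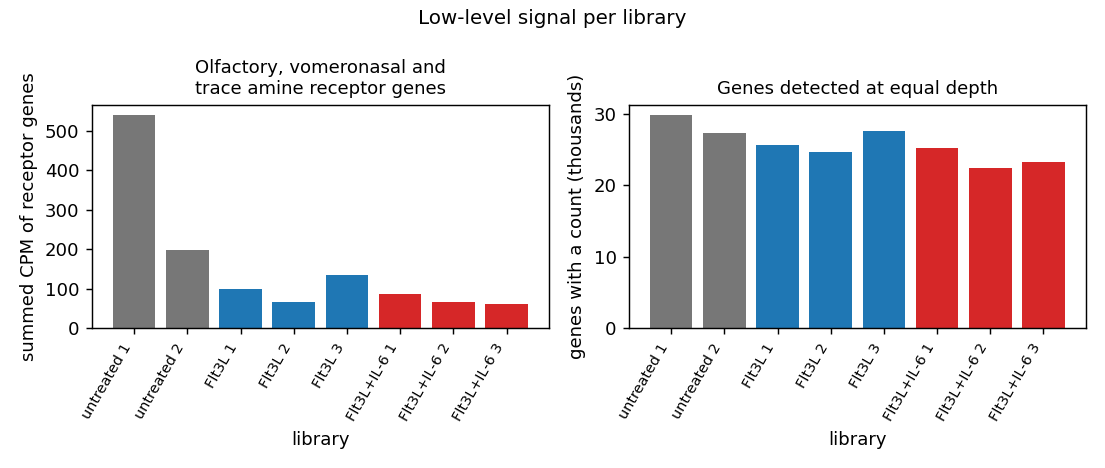
Left, summed CPM of 1669 olfactory, vomeronasal and trace amine receptor genes in each of the 8 libraries, and right, genes with a count after thinning to the smallest total (gray untreated, blue Flt3L, red Flt3L plus IL-6). Both untreated libraries, at 539 and 197 CPM, lay above every treated library on the left, of which the highest was Flt3L replicate 3 at 135; on the right Flt3L replicate 3 (27613) lay above untreated replicate 2 (27349).

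Of 25 IL-6 and STAT3 targets 13 rose, also 13 when adjusted over the list alone, where 2 fell (camera adjusted p = 4.20e-10, fry 0.00536; adjusted p = 0.0819 with an estimated correlation). The number was 5 without untreated replicate 1 and 7 without IL-6 replicate 2. Of 23 cholesterol synthesis genes 21 rose, and 22 when adjusted over the list alone (median 3.28; camera adjusted p = 3.18e-38, fry 0.00193; adjusted p = 0.0819 with an estimated correlation). Of 18 MHC class II and maturation genes 10 rose and 1 fell, among them Cd74 (125 ± 5.62 to 859 ± 135 CPM) and H2-Eb1 (6.41 ± 0.857 to 55.4 ± 10.6 CPM); adjusted over the list alone, 10 rose and 4 fell. The list had a camera adjusted p of 2.45e-07, fry 0.00369 and adjusted p = 0.107 with an estimated correlation, and 7 members called without untreated replicate 1. Of 20 monocyte genes 8 rose and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.000581; adjusted p = 0.378 with an estimated correlation; 4 members without untreated replicate 1 and 2 without untreated replicate 2). Of 17 progenitor genes 5 fell and 1, Spi1, rose, and adjusted over the list alone 9 fell and 1 rose (camera adjusted p = 0.0108; adjusted p = 0.319 with an estimated correlation, and 0.325 by camera without untreated replicate 2). Without untreated replicate 1 or 2 there were 3 called members. Cd93, a surface receptor of early progenitors, fell from 460 ± 4.20 to 176 ± 7.89 CPM. The call of Spi1 was lost without untreated replicate 1 (adjusted p = 0.152).

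Of 21 cDC1 genes 3 rose and 2 fell, and adjusted over the list alone 6 rose and 4 fell (camera upward, adjusted p = 0.0355; adjusted p = 0.252 with an estimated correlation, and by camera 0.0791 without untreated replicate 1, 0.0646 without Flt3L replicate 3 and 0.0636 without IL-6 replicate 3). Without untreated replicate 1 there were 2 called members, and 3 without untreated replicate 2 or IL-6 replicate 2. Id2 and Naaa, an amidase of cDC1 (29.1 ± 2.10 to 91.7 ± 11.4 CPM; lost without untreated replicates 1 or 2, with adjusted p up to 0.0550), rose while Irf8 fell. Plasmacytoid genes had a median of -0.17 and a mean of 0.12 with an upward camera direction (adjusted p = 0.976), and IL-6 induced secreted genes a median of -0.53 and a mean of 0.26 (upward, adjusted p = 0.272). Of 20 p53 targets 7 rose, and 11 with 1 lower when adjusted over the list alone, and this was the only list called with an estimated correlation (adjusted p = 0.0368); 3 members were called without untreated replicate 1 and 4 without untreated replicate 2. Cdkn1a reached 203 ± 10.6 CPM. Of 22 NF-kB genes 9 rose, of 24 glycolysis genes 8 and of 24 stress response genes 7, and adjusted over each list alone 11, 15 and 15 did. Their camera adjusted p was 1.65e-07, 4.20e-10 and 4.20e-10, and adjusted p = 0.219, 0.219 and 0.157 with an estimated correlation. Without untreated replicate 1 these counts were 2, 0 and 2, without untreated replicate 2 they were 4 each, and without IL-6 replicate 2 they were 4, 5 and 3. NF-kB genes also fell to 4 called members without IL-6 replicate 1, and the glycolysis and stress counts were 14 and 11 without Flt3L replicate 3. Dntt fell from 107 ± 37.5 to 9.98 ± 2.51 CPM, and Klrd1 rose to 188 ± 16.2 CPM, so that markers of lymphoid cells moved in both directions.

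Of 28 MYC and ribosome biogenesis genes 5 rose, of 26 G2 and M phase genes 4, of 24 immediate early genes 4, of 25 growth factor receptor feedback genes 3 and of 7 C/EBP family genes 2. Their camera adjusted p was 4.20e-10, 4.13e-07, 7.39e-06, 0.00344 and 0.00118, and adjusted p = 0.219, 0.287, 0.160, 0.221 and 0.107 with an estimated correlation. Without untreated replicate 1 the first 4 counts were 0, 0, 2 and 0, and without IL-6 replicate 2 they were 0, 0, 1 and 0. The first 3 were 2 each without Flt3L replicate 1, and the first 2 were 1 each without IL-6 replicate 1 and 3 and 0 without untreated replicate 2; the immediate early count was 7 without Flt3L replicate 3. Downward calls were those of B cell genes (1 of 14 fell; camera adjusted p = 0.00350; adjusted p = 0.107 with an estimated correlation) and of neutrophil and granule genes (2 of 20 fell; 0.0263 and 0.557). Of the latter, Mpo was lost without untreated replicate 2 or IL-6 replicate 1 (up to 0.0707). In the C/EBP family, Cebpb was lost without untreated replicate 1 (0.0655) and Cebpd without untreated replicate 2, Flt3L replicate 1 or IL-6 replicates 1 or 2 (up to 0.116). The neutrophil list was lost without untreated replicates 1 (0.0791) or 2 (0.120) or IL-6 replicate 3 (0.0587).

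Leaving out libraries reduced the 1271 calls to 282 without untreated replicate 1, 561 without untreated replicate 2, 508 without IL-6 replicate 2, 796 without Flt3L replicate 1 and 815 without IL-6 replicate 1. Of 17 lists called by camera, 1 held with an estimated correlation and 10 by fry. The larger share fell with DESeq2 (1767 up, 2191 down), voom (834 up, 965 down), no filter (1497 up, 1655 down) and a filter of 5 CPM (496 up, 568 down). The authors' deposited table had 2054 calls (1191 up, 863 down). Of the 1205 genes called here that it lists, it called 1109, all in the same direction. With scaling factors from genes of at least 10 CPM the split was 410 up and 883 down, as the median of all genes moved from -0.22 to -0.57.

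Both treated groups were kept for 6 h, so the comparisons are no sequence in time. Whether the change with IL-6 ran with or against the change with Flt3L was described from the first 2 comparisons, which share the Flt3L libraries with opposite sign. The covariance of their log2 fold changes across 24780 genes was -0.0867, against -0.278 (SD 0.00601) for 100 simulated sets of unchanged groups, a difference of 0.191. The correlations were -0.0834 and -0.440. Simulated genes varied independently, so the SD leaves out effects shared by the genes of a library. The difference therefore cannot be judged against that SD. With each library left out, and unchanged groups simulated for the 7 others, the difference was 0.0380 without untreated replicate 1 (-0.235 against -0.273, SD 0.00653), 0.290 without untreated replicate 2 (0.00245 against -0.288), 0.153 without Flt3L replicate 3 (-0.259 against -0.412) and 0.147 to 0.293 without any of the others. Of 90 genes that rose with IL-6, 8 were also higher in Flt3L than in untreated cells, where independent lists would share 0.556, and 2 (Il6st and Gbp7) were lower (0.0799 for independent lists). Of 30 genes that fell with IL-6, 2 were higher (0.185) and 1, Il31ra, was lower (0.0266). The values for independent lists allow neither for the shared libraries nor for genes of low dispersion, which pass more readily in both comparisons. Chance differences in the shared Flt3L libraries move the comparisons in opposite directions, so they could add to the overlaps of opposite direction and not to the others.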

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

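The number of genes called between Flt3L plus IL-6 and Flt3L (120) was 672 with no filter on low counts, 265 with a filter of 5 CPM, 760 with DESeq2, 408 with voom, and 45 at an adjusted p under 0.01. For Flt3L against untreated (175) the numbers were 909 with no filter, 1386 with DESeq2, 910 with voom and 80 at the stricter threshold. For Flt3L plus IL-6 against untreated (1271) they were 3152 with no filter, 3958 with DESeq2, 840 with only the 2 groups compared and 329 at the stricter threshold. The cause was not tested, apart from the stricter threshold, which lowers a count by construction.

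With each library left out, the first count lay between 45 and 185, the second between 85 and 401 and the third between 282 and 1545. With untreated replicate 1 and IL-6 replicate 2 left out together they were 79, 93 and 199, and calls that held with each library left out were lost for Siglech (adjusted p = 0.0849) and Cdkn1a (0.0927) between Flt3L and untreated cells and for Ccr2 (0.0535), Ctsg (0.0622), Cd93 (0.116), Bax (0.140) and Atf4 (0.144) between Flt3L plus IL-6 and untreated cells. With either untreated library left out, the other was assumed to vary like the remaining groups. Lists called by camera (13, 14 and 17) numbered 0, 1 and 1 with an estimated correlation and 1, 3 and 10 by fry. Between Flt3L plus IL-6 and Flt3L that correlation was 0.413 for MYC and ribosome biogenesis and 0.256 for the stress response, well above the preset 0.01. The C/EBP family, at -0.00369, lost its call as well. With each library left out they numbered 8 to 15, 14 to 17 and 15 to 17. The cause was not tested.

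With a block for replicate number the counts were 111, 159 and 909 and the lists 13, 14 and 17, of which the neutrophil list was not called in either comparison with untreated cells. The calls of Cebpb (adjusted p = 0.0522), Il6st (0.0854), H2-DMa (0.0863) and Slc2a1 (0.0607) between Flt3L plus IL-6 and Flt3L were lost with the block. So were those of Il6st (0.0973), Flt3 (0.0505), Ctsg (0.0556) and Ccnd2 (0.0596) between Flt3L and untreated cells, and of Tlr12 (0.103) and Ly6d (0.0558) between Flt3L plus IL-6 and untreated cells. The correlations of deviations from group means between same-numbered libraries were -0.0231, 0.00838 and -0.120 for Flt3L with IL-6, -0.0197 and 0.172 for untreated with Flt3L, and 0.194 and 0.0646 for untreated with IL-6. They had both signs, so a pairing by number was neither shown nor ruled out.

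With TMM factors from genes of at least 10 CPM, 54.2%, 75.6% and 31.7% of the called genes rose, against 75.0%, 87.4% and 57.4% by the factors from all tested genes. For Flt3L plus IL-6 against untreated, the share that rose was also 44.6% with DESeq2, 46.4% with voom, 47.5% with no filter and 46.6% with a filter of 5 CPM, and for Flt3L against untreated 47.7% with voom. For Flt3L plus IL-6 against Flt3L the share that rose was 55.85% with a filter of 5 CPM, 64.3% with DESeq2, 66.8% with no filter and 73.5% with voom. The balance of rises and falls thus depends on scaling, test and filter. With those TMM factors the calls of Ifitm3 (adjusted p = 0.0601) and Nfkbia between Flt3L and untreated cells were lost, and of Cebpd (0.0893) and Bcl6 (0.0551) between Flt3L plus IL-6 and untreated cells.

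With only the 2 groups compared, calls between Flt3L and untreated cells were lost for Flt3 (0.0820), Il6st (0.0750), Hmox1 (0.0643), Ctsg (0.0578), Ccnd2 (0.0533), Ifitm3 (0.0519), Bax (0.0508) and Aldoa (0.0505), between Flt3L plus IL-6 and untreated cells for Cebpd (0.0794), Bcl6 (0.0652) and Junb (0.0554), and between Flt3L plus IL-6 and Flt3L for Sec31b (0.0751).

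The covariance of the IL-6 change with the Flt3L change (-0.0867) was -0.000199 with a filter of 5 CPM (-0.0621 for simulated unchanged groups under that filter, a difference of 0.0619) and -0.259 to 0.00245 with each library left out, at 0.0380 to 0.293 above groups simulated as unchanged for the libraries kept. Genes with little change also turned sign. Between Flt3L plus IL-6 and Flt3L, the log2 fold change of Csf1r (0.12) was -0.00129 with a filter of 5 CPM, -0.0391 with voom, -0.00330 with TMM factors from genes of at least 10 CPM and -0.236 to 0.342 with each library left out, with -0.198 without Flt3L replicate 3. Cebpa (0.27) was -0.109 with both libraries left out together and -0.150 to 0.780 with each left out, with -0.112 without IL-6 replicate 2. Klf4 (-0.06) ranged from -0.172 to 0.0490, with 0.0339 without Flt3L replicate 3. Against untreated cells, Zeb2 (-0.16) ranged from -0.437 to 0.211, with 0.00888 without IL-6 replicate 3, and Il6st (-0.12) from -0.396 to 0.246. The cause was not tested.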

Other observations

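The genes in the first paragraph were chosen after the values were seen. The tests of background reads in genes under 5 CPM, of such reads as the cause of every fall at 5 CPM or more, and of expression trend for cholesterol synthesis genes were also chosen after their results were seen; the other tests were fixed before.

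Among the genes that rose with IL-6 over Flt3L were receptors and matrix genes outside the fixed lists. Ccr5, a chemokine receptor, went from 19.2 ± 1.55 to 166 ± 13.2 CPM (log2 fold change 3.11, SE 0.23, adjusted p = 6.35e-05 by edgeR's quasi-likelihood test) and Ccr1 from 38.5 ± 12.9 to 145 ± 23.0 CPM. Csf2rb, the shared chain of the GM-CSF, IL-3 and IL-5 receptors, went from 369 ± 73.7 to 1114 ± 146 CPM, although its reads are uncertain against its paralog Csf2rb2. Tgfbi, a secreted matrix protein, went from 234 ± 124 to 1847 ± 372 CPM and Adam9, a membrane protease, from 11.4 ± 1.28 to 54.9 ± 11.3 CPM. These 5 calls held with each library left out, at an adjusted p of 0.0498 at the highest. Of the 9 genes looked at, the calls of Csf2rb2 (up to 0.0721), Spp1 (0.0743), Mmp14 (0.141) and Mmp19 (0.0921) were lost with a library left out. Il31ra stood at 51.9 CPM in untreated cells, 7.93 with Flt3L and 1.56 with Flt3L plus IL-6.

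The first pattern was the 541 genes that fell in Flt3L plus IL-6 against untreated cells, where background reads spread over silent genes may have added to the untreated libraries. Of the 247 genes under 5 CPM, 87.9% dropped no further than receptor genes do at their 99th percentile, but 140 could not exceed it at their length, and of the 107 others 77 did not. That share was thus largely fixed by the choice of genes, and background and a fall in expression cannot be told apart. Of the 294 at 5 CPM or more, 164 dropped further than that percentile and 26.5% further than any receptor gene, so background did not cause every fall, while for the 44.2% within the percentile it cannot be told apart from a fall in expression. The difference in total count did not account for most of the falls. With every library thinned once to the smallest total, 470 of the 541 genes (86.9%) were still lower. In all, 693 genes fell and 925 rose after thinning.

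The second pattern was the rise of cholesterol synthesis genes with Flt3L. A trend with expression level or scaling did not account for the whole rise. The list median of 3.01 lay at percentile 100 of matched random lists, whose central range was 0.0727 to 0.482. Under the scalings tried it was at least 2.80. Less sterol in the treated medium could raise these genes. Of 9 targets of the sterol sensor LXR, 1 passed as lower (Abcg1) and none as higher, with 4 estimates lower and 5 higher. This explanation, a direct effect of Flt3L and an effect of other contents of the conditioned medium thus cannot be told apart. Time in culture rather than Flt3L cannot be told apart either, because both treated groups spent 6 h in culture, with a list median of 0.28 between them.

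The third pattern was the upward lean of MYC and ribosome biogenesis genes and of stress response genes with IL-6, which may reflect growth or protein load. No member of either list passed over all genes. Neither list was called by camera with an estimated correlation (adjusted p = 0.213 and 0.189) or by fry (0.107 and 0.0594). A trend with expression level or scaling did not account for the whole of either list median, though it may account for a part. The medians were 0.640 and 0.661, at percentile 100 of matched random lists. Central ranges of the random lists were -0.00773 to 0.313 and -0.0874 to 0.307. Under the scalings tried the medians were at least 0.492 and 0.510. The random lists drew genes independently while list members vary together, so the percentile is no p-value. Flt3L replicate 3 alone was excluded as the source, since the medians kept at least 0.923 of their size without it; without IL-6 replicate 3 they were 0.41 and 0.49. For the 120 genes called in this comparison, 1 of 10 splits of the 6 libraries, the real one, called as many, and the highest other called 1; 10 splits are too few for a share under 0.05.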
